A study of Mus musculus with 10 samples.

How the data were processed

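RNA was measured in pDC sorted from mouse spleen, in 10 samples of 5 groups with 2 samples each. Per the labels' protocols, spleen cells were gated as negative for CD3, CD19, Ly6G, NK1.1 and CD11b, low for CD11c and high for CD317, and then by CD86 and YFP. RNA of 3 to 20 ng was amplified with a whole-transcript kit, labelled with biotin and hybridised to 1-colour Affymetrix arrays. Mice were infected for 1.5 days, per the labels. The deposited values are log2 signals per probe set that the authors made by RMA with the oligo package, per the submitters' processing notes; versions, and which arrays were normalized together, are not given in the sources used here. RMA brings the value distributions of arrays close to each other, so a change shared by most genes of a group would not show. The values carry no detection call, so the fold of a gene whose lower group lies near the background of the array is understated, and genes near the highest values of 13.5 to 13.7 may be compressed.

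The table held 35556 probe sets in all 10 samples. The platform annotation paired 21789 of them with 1 gene symbol and 1621 with several, and 12146 were not listed. Entrez identifiers of 21698 single-gene probe sets were found in the RefSeq gene table of assembly GRCm38.p6, which was used for current symbols only, and 91 kept the platform's symbol. No build was named for the array, so no coordinates are printed. For each gene the probe set with the highest mean over the 10 samples was kept, which gave 19938 genes, 999 of them with more than 1 single-gene probe set. Genes of families with near-identical copies (interferon-alpha, Ifit3, immunoglobulin and MHC genes) can share probes, and their values are uncertain.

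Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited log2 values as they stood, with all 10 samples and no covariate, so that the groups shared 1 estimate of the spread from 5 residual degrees of freedom and 3.92 prior degrees of freedom. Of the 7 contrasts, 2 compared infected with uninfected cells, 2 compared CD86+ with CD86- cells, 2 compared YFP+ with YFP- cells and 1 took the difference between the infection effects. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. Folds are 2 to the power of the fitted log2 difference. With 2 samples per group the p-values rest on the pooled spread, and samples were pools of mice from separate sortings.

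Before the data were examined, 23 gene lists with 404 genes were fixed, of which 354 were measured, 27 lay only on probe sets of several genes and 23 were not listed. The lists covered interferon-stimulated genes, interferon genes, cytokines and chemokines, dendritic cell maturation, MHC class I, MHC class II, pDC identity, conventional and transitional dendritic cells, endosomal Toll-like receptor signalling, NF-kB targets, the unfolded protein response, the cell cycle, sterol biosynthesis, glycolysis, cell death, and immediate early genes, and markers of B cells, plasma cells, T cells, NK cells, neutrophils, monocytes and macrophages, and erythroid cells. Lists with at least 3 measured genes were tested with limma's camera at its preset correlation of 0.01, adjusted over 154 tests of 22 lists. Of these, 74 passed with the preset correlation, 0 with the correlation estimated from the data and 34 with limma's fry, which tests whether a list's genes move one way and does not compare them with other genes. The erythroid list had too few measured genes for a test.

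Genes were named by a rule fixed at the same time. It took the 10 largest rises and the 10 largest falls past the threshold with both samples of a group above both of the other (for the difference of infection effects, with both replicate-wise differences of the same sign). It added up to 4 genes per list with the largest difference past the threshold, or up to 2 where none passed, and the sorting genes Cd86, Ifnb1, Ifnar1, Bst2 and Itgax. Gene models without a name and microRNA genes were counted and not described. The immunoglobulin genes as a group, the library values of S100a8, S100a9, Cdk1, Cxcl9, Lyz2 and Fcer2a, and the genes Ifnk, Siglech, Igha, Cldn13, Rhag, Tfrc, Gfi1b, Aqp1, Tal1 and Lta were chosen after values had been seen. The overlap of 2 sets of called genes was set beside the product of their sizes divided by the number of genes tested, for comparisons that share no library. The comparisons still share the estimate of the spread of each gene, which can raise overlaps above that product. Infected libraries also shared some variation by replicate number, so lists from different infected groups are not independent.

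The fit was tested on simulated data drawn around the mean of each of the 19938 genes over all samples with the spread of that gene within groups, without true differences except for those added, with 50 genes changed at each of 4 sizes. For infection in CD86-YFP- cells it recovered 26% of changes of 0.5 log2 units, 76% of 1, 98% of 2 and 100% of 4, with 5 false calls among 155. For YFP+ against YFP- cells it recovered 32%, 88%, 100% and 98% of the same sizes, with 6 false calls among 165. For the difference of the infection effects it recovered 0%, 66%, 98% and 98%, with 5 false calls among 136. The noise was drawn independently for each gene and library. The rates therefore do not cover variation shared between genes or libraries, or single libraries with transcripts of other cells.

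The alternatives fixed in advance were the replicate number as a block, a trended robust variance, array weights, only the compared groups in the fit, leaving out the 40% of genes with the lowest mean, the mean of a gene's probe sets, every probe set, cyclic loess, scaling on 57 ribosomal protein genes, a fold threshold of 1 log2 unit, leaving out each library in turn, leaving out the 2 libraries labelled Ifnar1-deficient, and for lists the estimated correlation and fry. Fits without the 3 infected libraries of replicate 2, and without immunoglobulin genes and Jchain, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.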

Results

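Gene expression was measured in plasmacytoid dendritic cells (pDC), immune cells known for producing large amounts of type I interferon, from the spleens of mice that carry a yellow fluorescent protein (YFP) reporter in the interferon-beta gene Ifnb1. Mice were left uninfected or were infected for 36 hours with murine cytomegalovirus (MCMV), a herpesvirus of mice. The pDC were sorted by CD86, a costimulatory surface protein of activated cells, and by YFP, which marks cells that switched on Ifnb1. The 10 libraries fell into 5 groups of 2: uninfected CD86-YFP-, uninfected CD86+YFP-, infected CD86-YFP-, infected CD86+YFP- and infected CD86+YFP+ cells. Each library came from 10000 sorted cells pooled from 4 uninfected mice or from 10 to 12 infected mice, and the 2 libraries of a group came from separate sortings, per the labels. Each library was hybridised to 1 array, and the number of arrays limits the precision. Median log2 signals ran from 4.45 to 4.54 over the 10 arrays. The 2 libraries of a group correlated across probe sets with r between 0.981 and 0.989, where probe sets are not independent replicates.

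The sorted proteins were read first at the transcript level, as a check of the labels and not as a finding. Ifnb1 averaged 3.88 ± 0.10 (SD, n = 2) in uninfected CD86-YFP- cells and 4.11 ± 0.19 (SD, n = 2) in uninfected CD86+YFP- cells on the log2 scale. It averaged 12.50 ± 0.10 (SD, n = 2) in infected CD86+YFP+ cells, above the 8.38 ± 0.39 (SD, n = 2) and 8.66 ± 0.29 (SD, n = 2) of the infected CD86-YFP- and CD86+YFP- cells. Cd86 was 2.41 log2 units higher in infected CD86+YFP- than in infected CD86-YFP- cells (SE 0.20, adjusted p = 0.0150). In uninfected mice the Cd86 difference was 0.92 (SE 0.20) and did not pass (adjusted p = 0.322). Bst2, which encodes the sorting marker CD317, averaged between 12.24 and 12.50 in the 5 groups. Itgax, which encodes the sorting marker CD11c, fell with infection by 1.11 log2 units in CD86-YFP- cells (SE 0.20, adjusted p = 0.0126) and by 0.97 in CD86+YFP- cells, and its group means ran from 8.44 in uninfected CD86-YFP- to 6.87 in infected CD86+YFP- cells. A label of the CD86+YFP- libraries of replicate 1, uninfected and infected, calls the cells deficient in Ifnar1, a chain of the type I interferon receptor, while the titles and the design text do not. The same label gives CD45.2 cells for replicate 1 and CD45.1 cells for replicate 2 of every group, and a label of the mice speaks of mixed chimeras, so the origin of the cells is uncertain. In these libraries Ifnar1 measured 8.77 and 8.61, beside 8.95 and 8.60 in replicate 2 of the same groups. The mean of 33 type I interferon-stimulated genes was 9.44 in the infected library with that label and 9.56 in its partner, beside 6.39 and 6.14 in uninfected CD86-YFP- cells. In the uninfected library with that label it was 6.83, below the 7.16 of its partner.

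The first comparison set infected against uninfected pDC that were negative for CD86 and YFP. Infected CD86-YFP- cells carried a large antiviral response: 31 of the 33 measured type I interferon-stimulated genes rose and none fell, with a median of 3.28 log2 units (camera adjusted p = 1.32e-73). Adjusted over the list alone, 33 rose. The list's call was not kept with the correlation estimated from the data (adjusted p = 0.0603 with an estimated correlation). Ifit1, an inhibitor of viral translation, rose by 5.15 log2 units (SE 0.27, adjusted p = 1.25e-05), or 35.5-fold. Ifit2 rose 31.8-fold, Ifit3 31.5-fold and Rtp4 31.4-fold. Ifi213, a member of the Ifi200 family of interferon-inducible genes, rose 36.0-fold. Sct, which encodes the peptide hormone secretin, rose 36.9-fold, from 6.51 ± 0.02 to 11.72 ± 0.04 (SD, n = 2 each).

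Some interferon genes themselves rose in these YFP- cells. Of 14 measured type I and III interferon genes 7 rose and 1, Ifnk, fell, with a median of 1.22 (camera adjusted p = 1.16e-12, and adjusted p = 0.134 with an estimated correlation), and 10 rose and 1 fell adjusted over the list alone. Ifna4 rose by 5.11 log2 units (SE 0.20, adjusted p = 1.47e-06), Ifna2 by 4.89 and Ifnb1 by 4.50. Of 21 cytokine and chemokine genes 6 rose and none fell (median 0.47, camera adjusted p = 7.85e-10, and adjusted p = 0.186 with an estimated correlation), also 6 adjusted over the list alone. Cxcl10, a chemoattractant of T cells, rose 32.4-fold, Ccl3 11.6-fold, Tnf 9.64-fold and Tnfsf10, which encodes the death ligand TRAIL, 8.33-fold. Of 24 dendritic cell maturation and migration genes 6 rose and 3 fell (median 0.07, camera adjusted p = 0.00452, and adjusted p = 0.369 with an estimated correlation), and 9 rose and 3 fell adjusted over the list alone. The costimulatory receptor gene Cd40 rose 7.85-fold and Cd274, which encodes the checkpoint ligand PD-L1, 5.51-fold, while Marcks fell by 2.17 log2 units. Of 17 cell death genes 6 rose and none fell (median 0.35, camera adjusted p = 5.53e-05, and adjusted p = 0.0652 with an estimated correlation), also 6 adjusted over the list alone. Among them were Casp4, an inflammatory caspase (8.87-fold), and Mlkl, the executor of necroptosis (3.09-fold).

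Most of the sterol biosynthesis genes, and some genes of other lists, fell with infection in CD86-YFP- cells. Of 15 sterol biosynthesis genes 8 fell and none rose, with a median of -0.60 (camera adjusted p = 5.00e-10, and adjusted p = 0.0819 with an estimated correlation), and 11 fell adjusted over the list alone. Hmgcs1, an early enzyme of the pathway, fell by 1.22 log2 units (SE 0.15, adjusted p = 0.00196) and Dhcr7 by 1.29. Of 22 conventional and transitional dendritic cell genes 6 fell and 2 rose (median -0.20, camera adjusted p = 0.0284, and adjusted p = 0.186 with an estimated correlation), and 7 fell and 3 rose adjusted over the list alone. Cd209a, a C-type lectin gene, fell by 3.20 and Sirpa by 1.23, while the receptor tyrosine kinase gene Axl rose 6.61-fold. The largest fall among named genes was that of Ccr2, a chemokine receptor gene, by 3.36 log2 units (SE 0.19, adjusted p = 2.02e-05), or 10.2-fold lower. Clec4g fell by 3.23, Gria3 by 2.79 and Scd2, a fatty acid desaturase gene, by 2.51.

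The largest rise was that of Car1, a carbonic anhydrase gene abundant in erythroid cells, by 6.39 log2 units (SE 0.65, adjusted p = 5.48e-04), or 83.9-fold. Car1 measured 9.41 and 10.80 in the 2 infected CD86-YFP- libraries and between 3.40 and 5.80 in the other 8. The 12 measured immunoglobulin genes, Jchain included, moved in this comparison as well, with 6 that rose and a median of 2.92. Of 21 cell cycle genes 2 rose and none fell (median 0.58, camera adjusted p = 3.24e-09, and adjusted p = 0.351 with an estimated correlation), and 10 rose adjusted over the list alone. Their levels differed between the libraries, as for Cdk1 with 4.49 and 6.91. Across all 19938 genes, limma called 1064 at an adjusted p under 0.05 in this comparison, 531 higher and 533 lower. The count was 550 without uninfected CD86-YFP- replicate 1, 446 without replicate 2 of that group and 478 without infected CD86-YFP- replicate 2. The 3 infected libraries of replicate 2 held transcripts of the neutrophil genes S100a8 and S100a9. A fit without them leaves a lone library in each infected group, so its lower count cannot be tied to these transcripts.

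**Figure D1:**
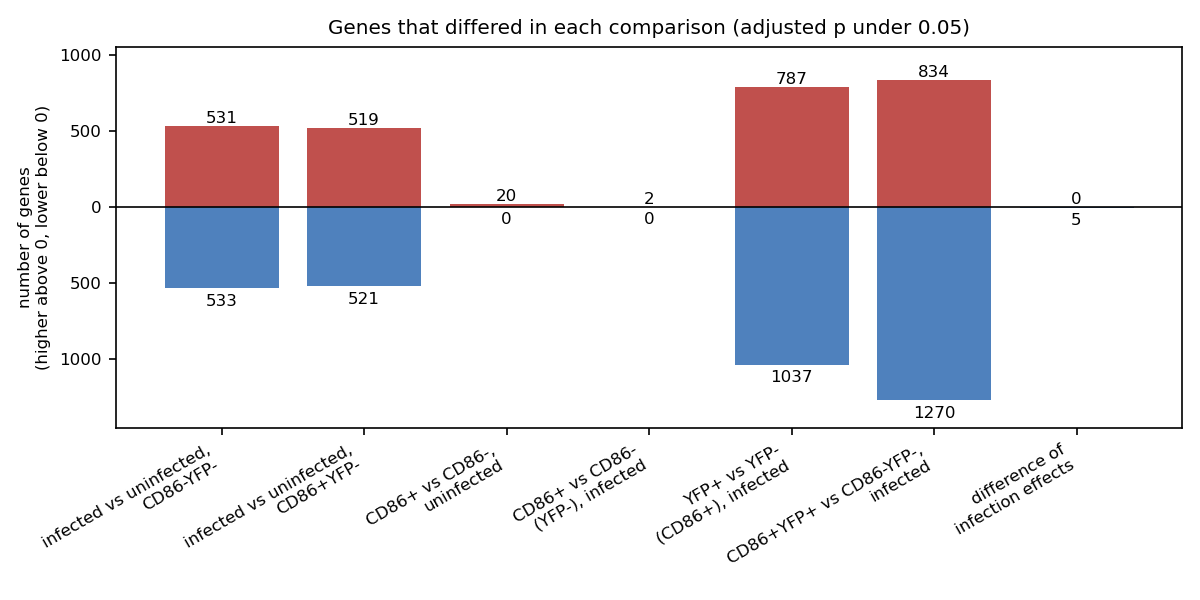
Number of genes past an adjusted p of 0.05 in each of the 7 comparisons (x axis), with genes higher in the first-named group above 0 and genes lower below 0 (y axis, number of genes). The comparisons of YFP+ cells with YFP- cells of infected mice gave the largest counts (1824 and 2104 genes), and the CD86 subsets of infected mice the smallest (2 genes).

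The second comparison asked what infection changed in CD86+ pDC without the reporter signal. Again 31 of the 33 interferon-stimulated genes rose and none fell, with a median of 2.70 (camera adjusted p = 2.71e-61, and adjusted p = 0.0603 with an estimated correlation), and all 33 rose adjusted over the list alone. Rtp4 rose by 4.47 log2 units (SE 0.22, adjusted p = 1.15e-05), or 22.1-fold, Ifit1 15.1-fold, Mx1 13.6-fold and Oas1a 12.7-fold. Of the 14 interferon genes 10 rose and none fell, with a median of 1.46 (camera adjusted p = 1.06e-17, and adjusted p = 0.0819 with an estimated correlation), also 10 adjusted over the list alone. Ifna2 rose by 6.07 (SE 0.23, adjusted p = 2.88e-06), or 67.2-fold, Ifna4 52.3-fold and Ifnb1 23.6-fold. Klk1b11, a kallikrein family gene, rose 20.7-fold. Of 18 NF-kB targets and feedback regulators 10 rose and 1, Sod2, fell (median 0.63, camera adjusted p = 5.62e-11, and adjusted p = 0.0603 with an estimated correlation), and 14 rose and 1 fell adjusted over the list alone. Gadd45b rose 2.82-fold and Cish, a feedback inhibitor of cytokine signalling, 2.34-fold. In CD86-YFP- cells 6 genes of this list rose with infection and 1 fell (median 0.55, camera adjusted p = 6.08e-10, and adjusted p = 0.0603 with an estimated correlation). Adjusted over the list alone, 11 rose and 1 fell there. The list did not pass for the difference of the infection effects (median 0.03, camera adjusted p = 0.489). Of the 24 maturation genes 9 rose and 2 fell (median 0.31, camera adjusted p = 9.09e-05, and adjusted p = 0.236 with an estimated correlation), and 11 rose and 2 fell adjusted over the list alone.

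Falls in CD86+YFP- cells included 9 of the 15 sterol biosynthesis genes, with none that rose and a median of -0.78 (camera adjusted p = 2.34e-14, and adjusted p = 0.0652 with an estimated correlation), and 14 fell adjusted over the list alone. Dhcr7 fell by 1.59 log2 units (SE 0.20, adjusted p = 0.00206) and Sqle, which encodes squalene epoxidase, by 1.19. Cd209a fell by 3.25, Ccr2 by 3.24, Clec4g by 3.13 and Scd2 by 2.99. Thy1 fell by 2.74, Abcg3 by 2.36 and Tet1, a DNA demethylation enzyme gene, by 2.35. S100a8 and S100a9, abundant in neutrophils, did not pass in this comparison, and S100a8 measured 4.29 and 8.28 in the 2 infected CD86+YFP- libraries. Immunoglobulin genes had a median of 0.22, with none of 12 that passed. Limma called 1040 of the genes, 519 higher and 521 lower. The count was 619 without uninfected replicate 1, 616 without infected replicate 1, 374 without infected replicate 2, 439 without the 2 libraries labelled Ifnar1-deficient, 632 with only the compared groups in the fit, and 302 without the 3 infected libraries of replicate 2. With arrays scaled on ribosomal protein genes, which moved the median of all genes to 0.11, 730 genes were higher and 315 lower.

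The infection responses of the 2 YFP- subsets, which share no library, overlapped. Their infected libraries shared some variation by replicate number (correlation of deviations 0.185), so the 2 responses are not independent. Of the genes that rose with infection, 365 rose in both subsets, where independent lists of these sizes would share 13.8. Of those that fell, 276 fell in both, beside 13.9 for independent lists. In opposite directions, 1 gene was called higher in CD86-YFP- and lower in CD86+YFP- cells. The test of the difference between the infection effects called 5 genes, all with a more positive infection effect in CD86-YFP- cells: Sct, Ifitm3, Apod, Iigp1 and Slc43a1. For Sct the difference was -2.66 (SE 0.17, adjusted p = 0.00212), for the antiviral membrane protein gene Ifitm3 -2.50 and for the lipocalin gene Apod -2.21. Sct averaged 9.33 ± 0.22 (SD, n = 2) in uninfected CD86+YFP- cells, above the 6.51 ± 0.02 (SD, n = 2) of uninfected CD86-YFP- cells, and lay at 11.88 ± 0.14 and 11.72 ± 0.04 (SD, n = 2 each) after infection. Cd86 itself averaged 5.70 in uninfected and 7.82 in infected CD86+YFP- cells, so a sorted subset need not hold the same cells before and after infection. The 33 interferon-stimulated genes had a median difference of -0.51 (camera adjusted p = 1.05e-19, and adjusted p = 0.144 with an estimated correlation). Of them 1 passed over all genes, lower, and 14 were lower and 1 higher adjusted over the list alone. The count of 5 was 2 without uninfected CD86-YFP- replicate 2, 1 without uninfected CD86+YFP- replicate 2, 47 without infected CD86-YFP- replicate 1 and 1 without infected CD86+YFP- replicate 1. It was 2 without the libraries labelled Ifnar1-deficient, 2 with only the compared groups in the fit and 1 with every probe set tested; ribosomal protein scaling, which moved the median of all genes to 0.11, gave 1 higher and 5 lower.

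**Figure D2:**
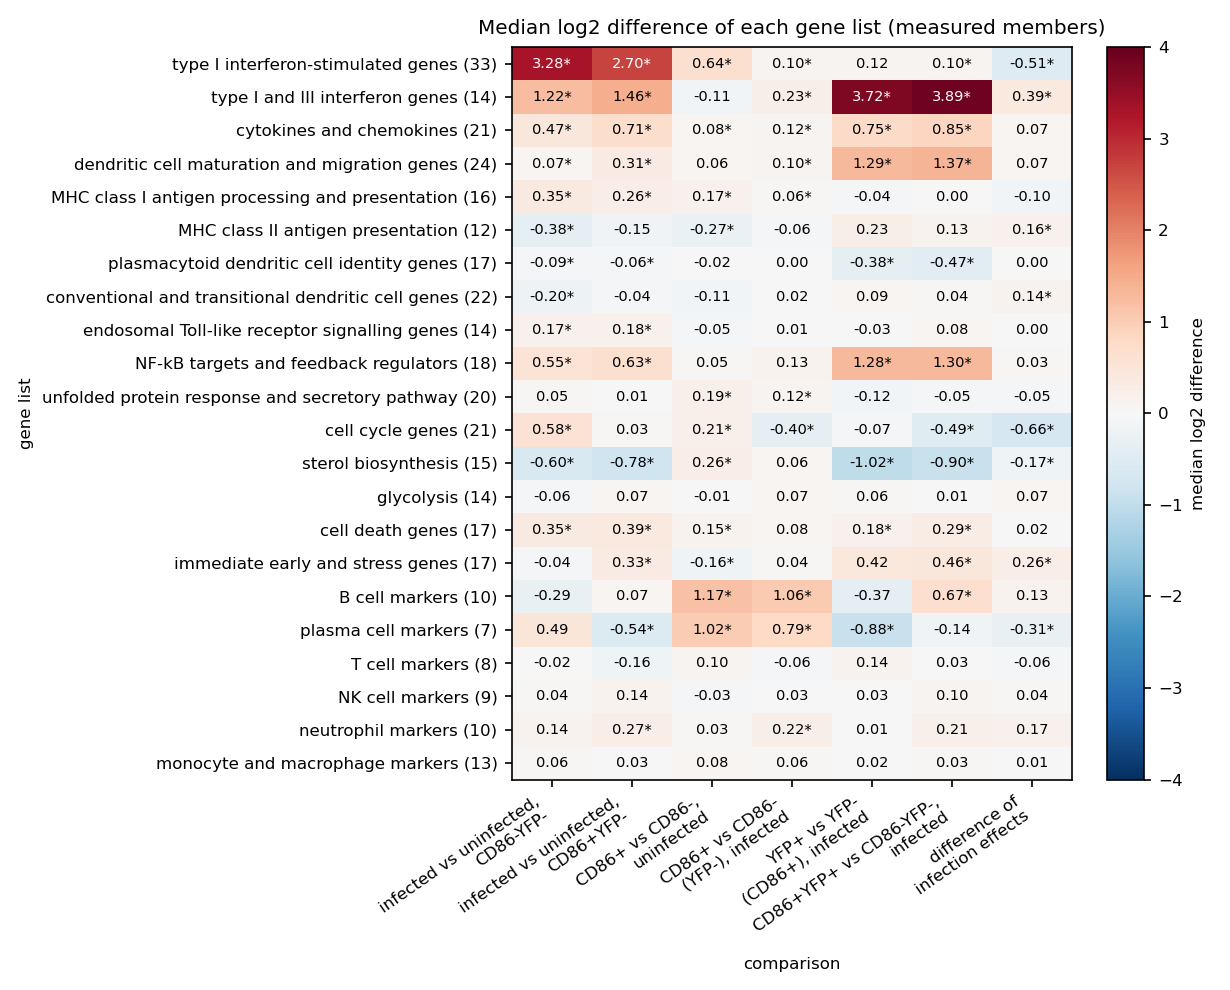
Median log2 difference of each gene list (y axis, number of measured members in parentheses) in each comparison (x axis), as colour and number; an asterisk marks a camera adjusted p under 0.05, and with an estimated correlation no list kept it. The interferon-stimulated genes had medians of 3.28 and 2.70 with infection and of 0.12 between YFP+ and YFP- cells, where the interferon genes had a median of 3.72.

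The third comparison asked how CD86+ and CD86- pDC differed without infection. Limma called 20 genes, all higher in CD86+YFP- cells, and 6 of these belong to the 12 immunoglobulin genes measured with Jchain. The kappa variable gene with the largest difference was 6.71 log2 units higher (SE 0.58, adjusted p = 0.00485), or 105-fold, Jchain, the joining chain of secreted antibodies, 58.3-fold and the heavy chain gene Ighm 32.6-fold. Tnfrsf17, a plasma cell survival receptor gene, was 4.17-fold higher. Of 7 plasma cell markers 2 were higher and none lower (median 1.02, camera adjusted p = 5.71e-11, and adjusted p = 0.0652 with an estimated correlation), and 5 were higher adjusted over the list alone. Of 10 B cell markers 1, Ighm, was higher and none lower (median 1.17, camera adjusted p = 3.24e-09, and adjusted p = 0.206 with an estimated correlation), and 3 were higher adjusted over the list alone.

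Beside these immunoglobulin transcripts, a few interferon-stimulated genes passed in uninfected CD86+YFP- against CD86-YFP- cells. Of the 33 genes 4 were higher and none lower, with a median of 0.64 (camera adjusted p = 3.94e-34, and adjusted p = 0.0806 with an estimated correlation), and 21 were higher adjusted over the list alone. Ifitm3 was 5.29-fold higher, Ifit2 2.87-fold, the nucleic acid sensor gene Zbp1 2.55-fold and Rsad2, which encodes the antiviral enzyme viperin, 2.13-fold. Sct was 7.05-fold higher (SE 0.12 log2 units, adjusted p = 6.34e-05), the tetraspanin gene Cd81 6.53-fold, Apod 5.57-fold, the chemokine gene Ccl5 2.98-fold and Cd40 2.66-fold. None of the 14 interferon genes passed in this comparison, with a median of -0.11 (camera adjusted p = 0.361). The count of 20 was 6 without uninfected CD86-YFP- replicate 1, 4 without replicate 2 of that group and 112, of which 54 were higher and 58 lower, without uninfected CD86+YFP- replicate 2. It was 17 without the libraries labelled Ifnar1-deficient, with 6 of the 20 genes among them, 13 without the immunoglobulin genes, 32 without the dimmest genes and 37 among every probe set.

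The fourth comparison set CD86+ against CD86- cells among the YFP- pDC of infected mice. Only 2 genes passed, Cd86 itself and Slfn1, a Schlafen family gene that was 3.01-fold higher in CD86+YFP- cells (SE 0.14 log2 units, adjusted p = 0.0150). With limma, 871 genes had an unadjusted p under 0.05, fewer than the 997 that no change at all would give on average with independent libraries. The fit ignored the variation that infected libraries shared by replicate number, which can lower that count. Il12b measured 6.37 ± 0.41 (SD, n = 2) in CD86+YFP- and 5.05 ± 0.39 (SD, n = 2) in CD86-YFP- cells and did not pass (difference 1.32, adjusted p = 0.204). Of the 14 interferon genes none passed, over all genes or adjusted over the list alone, and all 14 had a value above 0 (median 0.23, camera adjusted p = 1.06e-06, and adjusted p = 0.227 with an estimated correlation). Of the 10 B cell markers none passed over all genes and 7 were higher adjusted over the list alone (median 1.06, camera adjusted p = 3.97e-12, and adjusted p = 0.171 with an estimated correlation). Of the 7 plasma cell markers none passed over all genes and 1 was higher adjusted over the list alone (median 0.79, camera adjusted p = 4.89e-06, and adjusted p = 0.110 with an estimated correlation). The count of 2 was 59 (4 higher and 55 lower) without infected CD86-YFP- replicate 1, 1 (lower) without infected CD86+YFP- replicate 2 and 5 without the libraries labelled Ifnar1-deficient. It was 6 with a trended robust variance, 5 without the dimmest genes, and 0 with only the compared groups in the fit or with every probe set tested.

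The fifth comparison asked how pDC that switched on the Ifnb1 reporter differed from reporter-negative pDC with the same CD86 status. Il12b, which encodes a subunit of interleukin 12 and 23, rose by 5.90 log2 units (SE 0.21, adjusted p = 9.37e-07), or 59.6-fold, from 6.37 ± 0.41 to 12.27 ± 0.04 (SD, n = 2 each). Il6 was 56.0-fold higher, from 3.26 ± 0.18 to 9.07 ± 0.40 (SD, n = 2 each), Ccl5 26.8-fold and Il1b 23.4-fold. Of 21 cytokine and chemokine genes 10 were higher and 1, Tnfsf10, lower (median 0.75, camera adjusted p = 1.07e-09, and adjusted p = 0.186 with an estimated correlation), and 11 were higher and 1 lower adjusted over the list alone. Of the 14 interferon genes 12 were higher and none lower, with a median of 3.72 (camera adjusted p = 1.74e-23, and adjusted p = 0.0652 with an estimated correlation), also 12 adjusted over the list alone. Ifna12 was 34.2-fold higher, the type III interferon gene Ifnl2 33.6-fold and Ifnb1, the sorted gene, 14.3-fold. Interferon-alpha genes share near-identical sequence, so their probe sets may read each other's transcripts, and the values of single members are uncertain.

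Most of the maturation genes were higher in the YFP+ cells. Of 24 genes 15 were higher and none lower, with a median of 1.29 (camera adjusted p = 5.73e-17, and adjusted p = 0.0652 with an estimated correlation), and 18 were higher and 1 lower adjusted over the list alone. Tnfsf4, which encodes the ligand of OX40, was 15.5-fold higher, Ccr7, the receptor that guides dendritic cells to T cell zones, rose by 3.45 log2 units and Tnfsf9 was 10.2-fold higher. Marcks was 9.54-fold higher than in CD86+YFP- cells, in which it had fallen with infection. Of 18 NF-kB targets and feedback regulators 11 were higher and none lower (median 1.28, camera adjusted p = 4.02e-14, and adjusted p = 0.0603 with an estimated correlation), and 14 were higher and 1 lower adjusted over the list alone. Ier3 was 4.42-fold higher, Socs3 3.82-fold and Pim1 3.44-fold. Among cell death genes 4 of 17 were higher and 1 lower (median 0.18, camera adjusted p = 0.00252, and adjusted p = 0.110 with an estimated correlation), and 6 were higher and 1 lower adjusted over the list alone. Bcl2l1, which encodes the survival protein BCL-XL, was 15.4-fold higher, and Bcl2l11, which encodes the death-promoting protein BIM, 7.17-fold. Ch25h, which makes the antiviral oxysterol 25-hydroxycholesterol, was 23.9-fold higher, Hamp, the hepcidin gene, 23.7-fold and Tnip3 20.8-fold.

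Of the interferon-stimulated genes, 5 of 33 were higher in YFP+ than in YFP- CD86+ cells, with none lower and a median of 0.12 (camera adjusted p = 0.127, and adjusted p = 0.753 with an estimated correlation), also 5 adjusted over the list alone. Ifit1 was 2.99-fold and Ifih1 2.44-fold higher. Of 17 pDC identity genes 8 were lower and 1, Blnk, higher, with a median of -0.38 (camera adjusted p = 4.63e-07, and adjusted p = 0.196 with an estimated correlation), and 10 were lower and 1 higher adjusted over the list alone. Upb1 fell by 1.37 log2 units, Atp1b1 fell by 1.36 and Cox6a2 fell by 1.26. With infection, 2 genes of this list fell in CD86-YFP- and 3 in CD86+YFP- cells, and none rose. The medians were -0.09 and -0.06 (camera adjusted p = 0.0263 and 0.0284, and adjusted p = 0.530 in both with an estimated correlation). Cox6a2 averaged 12.4 and 12.7 in the uninfected CD86-YFP- and CD86+YFP- cells, and 11.6 in both infected YFP- subsets. Siglech, a surface marker of mouse pDC looked at after the values were seen, averaged 11.32 ± 0.14 in YFP+ and 11.95 ± 0.12 (SD, n = 2 each) in CD86+YFP- cells. Of 15 sterol biosynthesis genes 12 were lower and none higher (median -1.02, camera adjusted p = 2.47e-12, and adjusted p = 0.0676 with an estimated correlation), and 13 were lower adjusted over the list alone. Nsdhl fell by 1.30, Msmo1 by 1.27 and Cyp51 by 1.22.

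The largest falls from CD86+YFP- to CD86+YFP+ cells were those of immunoglobulin genes, of which 8 of 12 fell and none rose, with a median of -3.37. The same kappa variable gene fell by 6.05 log2 units (SE 0.58, adjusted p = 3.37e-04) and Jchain by 3.97. Of 7 plasma cell markers 2 fell and none rose (median -0.88, camera adjusted p = 0.00829, and adjusted p = 0.259 with an estimated correlation), and 4 fell adjusted over the list alone. Outside that family, Slpi, a protease inhibitor gene, fell by 2.37 and Smim5 by 2.19. Limma called 1824 genes in this comparison, 787 higher and 1037 lower, and 1590 with cyclic loess, 848 higher and 742 lower. With ribosomal protein scaling, which moved the median of all genes to 0.10, 1027 were higher and 791 lower. The count was 1144 without infected CD86+YFP- replicate 1, 1015 without replicate 2 of that group, 1037 without infected CD86+YFP+ replicate 2 and 374 without the 3 infected libraries of replicate 2.

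**Figure D3:**
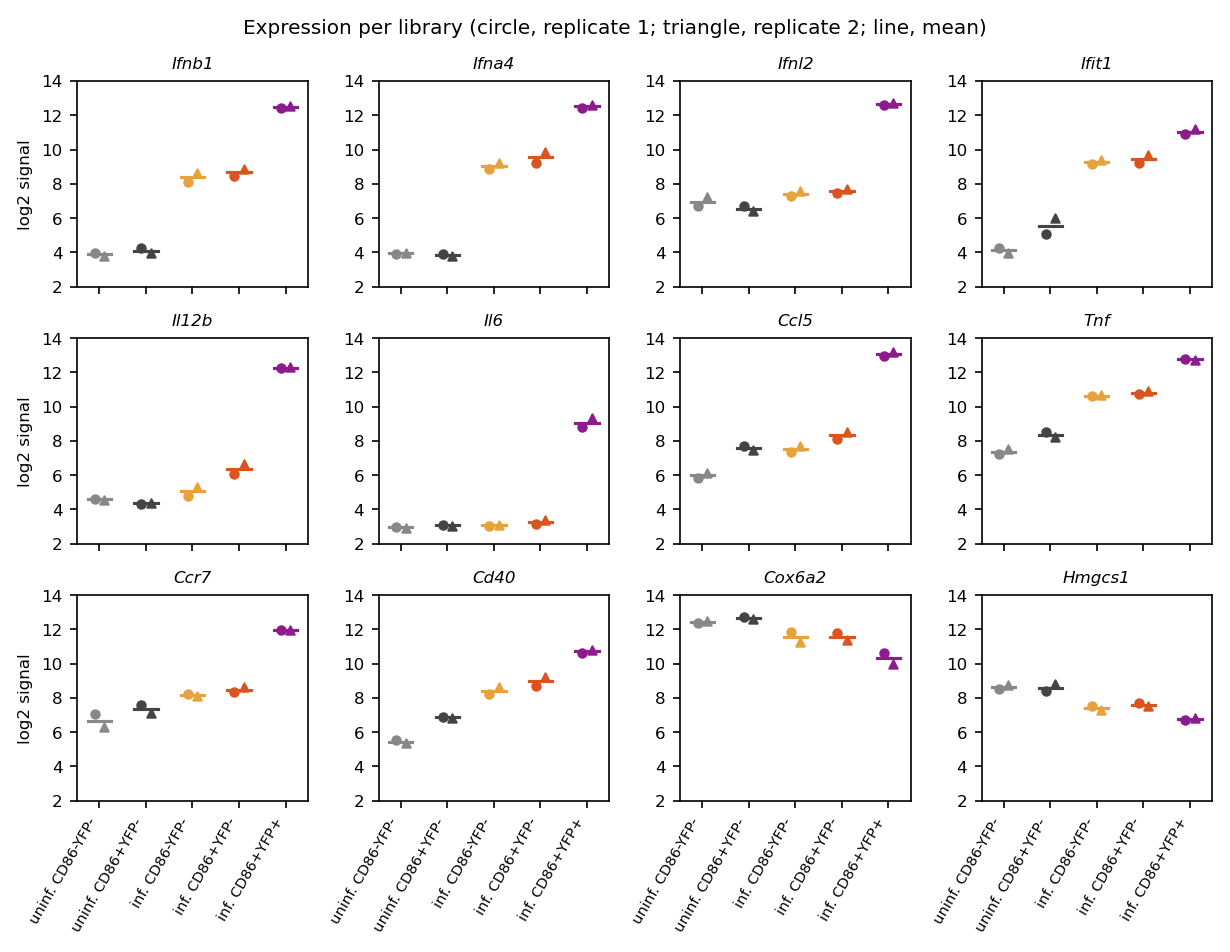
Log2 signal (y axis) of 12 genes in each library of the 5 groups (x axis); circles are replicate 1, triangles replicate 2 and lines the mean of 2 libraries. Il12b stood at 12.24 and 12.29 in the CD86+YFP+ libraries and at 6.66 or below in the other 8, while Ifit1 was already at 9.16 to 9.70 in the infected YFP- libraries.

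The sixth comparison set CD86+YFP+ against CD86-YFP- pDC of infected mice. Il12b was 149-fold higher (log2 difference 7.22, SE 0.21, adjusted p = 3.91e-07), Il6 63.6-fold, Ifna12 49.5-fold, Ccl5 46.8-fold and Ifnl2 37.3-fold. Of 24 maturation genes 17 were higher and none lower (median 1.37, camera adjusted p = 3.65e-21, and adjusted p = 0.0652 with an estimated correlation), and 19 were higher adjusted over the list alone. Among them were Tnfsf4 (14.9-fold), Ccr7 (13.8-fold) and the maturation marker Cd83 (11.3-fold). Of 17 pDC identity genes 9 were lower and 1 higher (median -0.47, camera adjusted p = 1.66e-06, and adjusted p = 0.206 with an estimated correlation), and 10 were lower and 1 higher adjusted over the list alone. The transcription regulator gene Id2 was 6.85-fold higher. Car1 fell by 5.58 log2 units, the metallothionein gene Mt2 by 2.89, Car2 by 2.87 and Jchain by 3.13, and 4 of the 12 immunoglobulin genes fell with none that rose. The B cell markers went the other way. None of the 10 passed, over all genes or adjusted over the list alone, and all 10 had a value above 0 (median 0.67, camera adjusted p = 0.00733, and adjusted p = 0.530 with an estimated correlation). Limma called 2104 genes, 834 higher and 1270 lower, against 994 and 815 with cyclic loess. With ribosomal protein scaling, which moved the median of all genes to 0.18, 1623 were higher and 729 lower. The count was 1396 without infected CD86-YFP- replicate 1, 1312 without replicate 2 of that group, 1220 without infected CD86+YFP+ replicate 2 and 575 without the 3 infected libraries of replicate 2.

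The step from YFP- to YFP+ among CD86+ cells was set beside the step from uninfected to infected CD86-YFP- cells, which share no library. Infected libraries of these groups shared some variation by replicate number, so the steps are not fully independent. Of the genes higher with infection, 117 were also higher in YFP+ cells, beside 21.0 for independent lists, and 52 were lower there, beside 27.6. Of the genes lower with infection, 154 were also lower in YFP+ cells, beside 27.7, and 38 were higher, beside 21.0. Marcks and Ciita, the master regulator gene of MHC class II, belong to the latter, with falls of 2.17 and 1.50 with infection and rises of 3.25 and 1.72 in YFP+ cells (all log2 units). Across genes, the differences of these comparisons correlated with r = 0.167, where genes are not independent replicates.

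**Figure D4:**
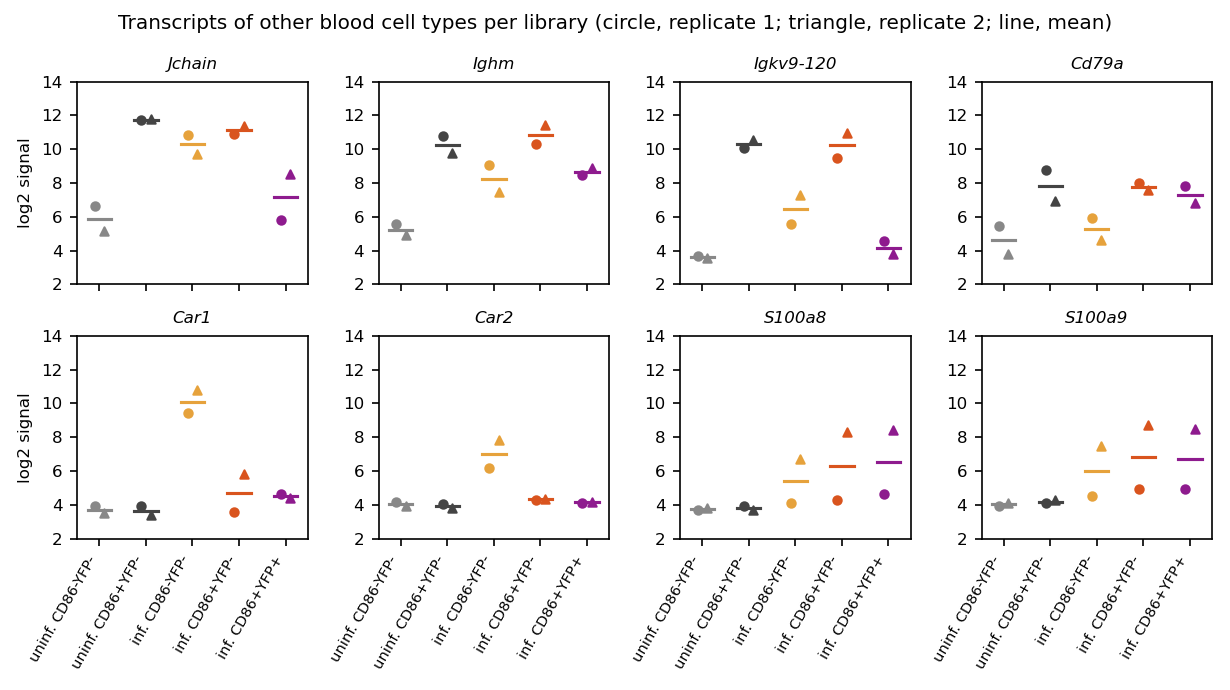
Log2 signal (y axis) of 8 genes abundant in other blood cells in each library of the 5 groups (x axis); circles are replicate 1, triangles replicate 2 and lines the mean of 2 libraries. Car1 was highest in the infected CD86-YFP- libraries (9.41 and 10.80), Jchain averaged 11.74 in uninfected CD86+YFP- cells, and S100a8 ran from 6.71 to 8.44 in the infected libraries of replicate 2 against 4.11 to 4.67 in those of replicate 1.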

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

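All tests of explanations in this part were chosen after the transcripts they concern had been noticed, the plasma cell, B cell, haemoglobin and YFP+ carry-over tests were set in their present form after their values had been seen, and only the erythroid progenitor test was written before its value was seen.

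The infection effect differed between CD86+YFP- and CD86-YFP- cells for 5 genes in limma's test of the difference itself, by -2.66 for Sct, -2.50 for Ifitm3, -2.21 for Apod, -1.80 for Iigp1 and -1.70 for Slc43a1 (log2 units). Sct, Ifitm3, Apod and Iigp1 were higher in uninfected CD86+YFP- than CD86-YFP- cells and lay close together in the infected subsets. Ifitm3 averaged 8.38 in CD86-YFP- and 10.78 in CD86+YFP- cells without infection, and 12.15 and 12.05 with it. For these genes the difference of effects largely restates the difference between the uninfected subsets. Among gene lists, camera with its preset correlation gave a difference for 8, with median log2 differences of -0.51 for interferon-stimulated genes, 0.39 for interferon genes, 0.16 for MHC class II genes, 0.14 for conventional and transitional dendritic cell genes, -0.66 for cell cycle genes, -0.17 for sterol biosynthesis, 0.26 for immediate early genes and -0.31 for plasma cell markers. With an estimated correlation none of the 8 passed, and for the cell cycle genes a single library stood apart, with a list mean of 6.54 in infected CD86-YFP- replicate 2 against 5.68 in replicate 1. Probe sets with several genes or no listed gene, 13767 in all, also passed the threshold: 165 and 168 with infection in CD86-YFP- and CD86+YFP- cells, 24 between the uninfected CD86 subsets, and 341 and 347 in YFP+ cells against CD86+YFP- and CD86-YFP- cells.

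Of 12 immunoglobulin genes, Jchain included, 6 were higher in uninfected CD86+YFP- than CD86-YFP- pDC, with Jchain at 11.72 and 11.75 against 6.61 and 5.13. Plasma cells among the sorted cells may be a source: the 6 plasma cell markers other than Jchain were higher as a list (median 0.91, unadjusted camera p = 0.00711 with an estimated correlation), and CD317, used in the gate, is also found on plasma cells. The whole plasma cell list, adjusted over all list tests, did not pass with an estimated correlation (camera adjusted p = 0.0652). For B cells the 9 markers other than Ighm gave an unadjusted camera p = 0.0913 with an estimated correlation (median 0.89), which left that source open, although the gate excluded CD19. Irf4 and Mzb1 of the plasma cell list are also expressed by pDC. A higher immunoglobulin expression by CD86+ pDC themselves stays open and was not tested.

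Car1 and Car2 were high in both infected CD86-YFP- libraries. Cldn13 measured 5.65 in replicate 2 but 4.175 in replicate 1, where the array median was 4.465. Car1, Car2 and Cldn13 did not pass against infected CD86+YFP- cells, where only Cd86 and Slfn1 did. Erythroid progenitors in that sort are a candidate source. The gate asked for CD11c and CD317, and whether such cells carried these after infection was not measured. None of 17 genes of that lineage passed against infected CD86+YFP- cells (lowest adjusted p = 0.204 with limma). As a list they lay higher (median 0.67, unadjusted camera p = 0.0214 with an estimated correlation). Rhag measured 3.61 and 6.08 against 2.91 and 3.02, but Tfrc differed by 0.05. Most of the 17 were higher in infected CD86-YFP- replicate 2 than in replicate 1, as for Gata1 with 5.09 and 4.19, so that library carried more of the shift. Against uninfected CD86-YFP- cells Gfi1b (1.06), Aqp1 (1.03) and Tal1 (0.52) rose and Tfrc fell by 0.94. Slc4a1 and Alas2 of the erythroid list fixed in advance did not pass in that comparison. Mature red blood cells were argued against, since 6 of the 8 other libraries had a higher mean of the haemoglobin probe sets than the lower infected CD86-YFP- library. This count, and its bound of 3 libraries, replaced the first deciding value after both had been seen; that value, the median difference of the haemoglobin probe sets between infected CD86-YFP- and CD86+YFP- cells, was -0.42 and lay within the spread of the replicates. Expression of Car1 by infected pDC was not tested apart from these.

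Ifnb1 was present in the infected YFP- cells, at 8.11 and 8.66 in CD86-YFP- and 8.46 and 8.87 in CD86+YFP- libraries. YFP+ cells in these sorts would need shares of 4.51% and 6.71%, and of 5.82% and 7.84%, to supply it on the linear scale. Over 17 genes with a low uninfected level, out of the 50 with the largest rise in YFP+ over CD86+YFP- cells, the median shares were 2.25% and 3.34%, and 2.74% and 7.55%, and the lower ratio to the share of Ifnb1 was 0.497 in CD86-YFP- and 0.471 in CD86+YFP- cells. Single genes differed. Il12b gave 0.0694% and 0.327% in CD86-YFP- and 0.890% and 1.58% in CD86+YFP- cells. Il6 gave 0.104% and 0.175%, and 0.205% and 0.510%. At the shares of Ifnb1, Il12b would lie at 7.94 and 8.47, and at 8.27 and 8.67. It measured 4.77 and 5.32, and 6.08 and 6.66, too low for cells with the mean CD86+YFP+ profile at those shares. Lta gave 6.08% and 8.95%, and 11.9% and 11.4%, above the shares of Ifnb1. A higher share is no sign of YFP+ cells, since YFP- cells may express the gene themselves. YFP+ cells as a source stay open, since the choice of genes favours small shares, the profile of YFP+ cells without CD86 was not measured and the test was redefined after earlier versions had been seen; Ifnb1 transcription in cells that had not yet produced YFP may contribute as well and was not tested.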

How the results depend on the processing

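The fits without infected replicate 2 libraries and without immunoglobulin genes were chosen after the data were seen. Counts are given in the order infection in CD86-YFP-, infection in CD86+YFP-, uninfected CD86 subsets, infected CD86 subsets, YFP+ against CD86+YFP-, YFP+ against CD86-YFP-, and the difference of infection effects, with 1064, 1040, 20, 2, 1824, 2104 and 5 genes. All 7 counts stayed within 1.5 times of these with array weights, the mean of probe sets, cyclic loess and ribosomal protein scaling. The first 2 of these settings test little. With 2 libraries per group the array weights were equal within each group, so no deviating library could count less than its partner. The mean of probe sets could change the values only of the 999 genes with more than 1 single-gene probe set, among 19938. No named gene or list reversed under an alternative run for it. Requiring a 2-fold difference left 447, 431, 615 and 708 genes for the 2 infection and the 2 YFP+ comparisons, by construction. With only the compared groups in the fit the counts were 632 for infection in CD86+YFP- cells, 0 for the infected CD86 subsets and 2 for the difference of effects. Without the dimmest genes (11963 tested) the uninfected and infected CD86 subsets gave 32 and 5. With every probe set these gave 37 and 0, and the difference of effects 1. A trended robust variance gave 6 for the infected CD86 subsets. Without the libraries labelled Ifnar1-deficient infection in CD86+YFP- cells, the infected CD86 subsets and the difference of effects gave 439, 5 and 2, with fewer samples, and the uninfected CD86 subsets 17, of which 6 were among the 20. Without the infected replicate 2 libraries, which leaves lone libraries, the 2 infection and the 2 YFP+ comparisons gave 377, 302, 374 and 575. Without immunoglobulin genes the uninfected CD86 subsets gave 13. The cause of the other moves was not tested.

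Leaving out each library in turn, with the lone library of its group assumed to vary like the others, gave ranges of 446 to 809, 374 to 1084, 4 to 112, 1 to 59, 1015 to 1471, 1220 to 1653 and 1 to 47. The replicate numbers did not pair the libraries of all groups (correlations of deviations from -0.16 to 0.26, 5 of 10 pairs over 0.1). The 3 pairs of infected groups had 0.149, 0.185 and 0.263, so infected libraries shared some variation by number, a number that the labels also tie to the CD45 allele. With the replicate block the counts were 1160, 1175, 28, 3, 1904, 2192 and 8, the last over 1.5 times its count of 5. The block was a single term shared by all groups. Uninfected CD86-YFP- libraries deviated opposite to the infected groups (correlations of -0.10, -0.16 and -0.14). These counts therefore do not settle what pairing of the infected libraries alone would give. Of the named genes that passed, 44 of 70, 40 of 71, 3 of 16 (Apod, Ifitm3 and Sct), 0 of 2, 52 of 75, 60 of 73 and 1 of 5 (Sct) passed under every alternative that was fixed in advance and run for genes. Over the alternatives other than leaving out 1 library, gene results kept their side of the threshold in 3636 cases, lost it in 274 and gained it in 18, and list shifts kept it in 303 and lost it in 141. Signal over background limits what the arrays show for dim genes, whose folds are understated.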

Other observations

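No test of an explanation is reported in this part; the library values of Cxcl9, Lyz2, Igha and Fcer2a were looked at after the results were seen.

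A minority of the antigen presentation and sensing genes passed with infection. In CD86-YFP- cells 6 of 16 MHC class I genes rose and none fell (median 0.35, limma camera adjusted p = 1.11e-08, and adjusted p = 0.144 with an estimated correlation), and 7 rose adjusted over the list alone. Nlrc5, the regulator of that class, rose 2.35-fold and the peptide transporter gene Tap1 2.25-fold. In CD86+YFP- cells 4 rose and none fell (median 0.26, camera adjusted p = 2.75e-05, and adjusted p = 0.215 with an estimated correlation), and 6 rose adjusted over the list alone. Of 12 MHC class II genes 1, Lgmn, rose and 1, Ciita, fell in CD86-YFP- cells (median -0.38, camera adjusted p = 0.00151, and adjusted p = 0.369 with an estimated correlation), and 1 rose and 6 fell adjusted over the list alone. Ciita fell by 1.50 log2 units there and was 3.30-fold higher in YFP+ than in CD86+YFP- cells. Of 14 endosomal Toll-like receptor signalling genes 3 rose and none fell in CD86-YFP- cells (median 0.17, camera adjusted p = 0.0254, and adjusted p = 0.206 with an estimated correlation), and 5 rose and 1 fell adjusted over the list alone. Tlr7, a sensor of single-stranded RNA, rose 1.74-fold and Tlr9, a sensor of unmethylated DNA, 1.54-fold. Of 17 immediate early genes 5 rose and none fell in CD86+YFP- cells (median 0.33, camera adjusted p = 3.52e-06, and adjusted p = 0.236 with an estimated correlation), and 6 rose adjusted over the list alone; Atf3 rose 4.18-fold and Egr1 3.14-fold.

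In YFP+ against CD86+YFP- cells, 3 of 20 unfolded protein response genes were higher and 2 lower (median -0.12, camera adjusted p = 0.432), with 3 higher and 3 lower adjusted over the list alone. Atf6, a stress sensor of the endoplasmic reticulum, was 2.69-fold higher and the chaperone gene Pdia4 fell by 0.91. Of 14 glycolysis genes 2 were higher and 1 lower (median 0.06, camera adjusted p = 0.535), with Pfkfb3 at 2.13-fold and Hk2 at 1.94-fold higher, and 3 higher and 2 lower adjusted over the list alone. Of 22 conventional and transitional dendritic cell genes 5 were higher and 4 lower (median 0.09, camera adjusted p = 0.864), with 5 higher and 6 lower adjusted over the list alone; Id2 was 4.53-fold and Axl 2.95-fold higher, and Clec10a fell by 1.64.

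Of the marker lists of other cells, the neutrophil list had no gene of 10 past the threshold with infection in CD86+YFP- cells (median 0.27, camera adjusted p = 0.0356, and adjusted p = 0.437 with an estimated correlation), and none adjusted over the list alone. S100a8 measured 6.71, 8.28 and 8.44 in the 3 infected libraries of replicate 2 and 4.11, 4.29 and 4.67 in those of replicate 1. For infection in CD86-YFP- cells the T cell list had 1 of 8 genes that rose and 1 that fell (median -0.02, camera adjusted p = 0.792), the NK cell list 1 and 1 of 9 (median 0.04, camera adjusted p = 0.360), and the monocyte and macrophage list 0 and 1 of 13 (median 0.06, mean -0.10, camera adjusted p = 0.939). Adjusted over the list alone these were 1 and 1, 1 and 1, and 1 and 2. The 2 measured erythroid list genes, Slc4a1 and Alas2, did not pass there, with differences of -0.03 and -0.21. Single libraries stood apart within the uninfected CD86+YFP- group, with Igha at 5.67 and 11.22, Lyz2 at 4.16 and 7.29, and Fcer2a at 7.01 and 3.57 in replicates 1 and 2. Cxcl9 measured 7.34 and 8.40 in the infected CD86-YFP- and CD86+YFP- libraries of replicate 2 against 4.83 and 4.79 in replicate 1.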
